A study of Mus musculus with 10 samples.

How the data were processed

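Cultured MC38 cells (5 libraries) and MC38.T4 cells (5 libraries) were measured by RNA sequencing. Per the labels' protocols, polyA-selected RNA was made into strand-specific libraries with a TruSeq stranded kit. The authors deposited 1 table of FPKM (fragments scaled by gene length and by the mapped fragments of the library), with 1 column per library and a gene symbol per row. The submitters' processing notes name the genome build GRCm39 and the tool DESeq2, with no version and no role for it. The aligner, the counting program, the gene annotation and any filter are not given in the sources used here. The table held 54343 genes, all columns were mapped to a sample by the library names in the labels, and no column was pooled. FPKM divides by gene length and by library total, so a few genes that take a larger share in 1 line lower all others, and values do not keep the read counts behind them. Sums of FPKM lay between 442183 and 484461. Read totals are not given, so no counting interval could be attached to a value; the spacing of low values gave relative depths from 0.874 to 1.14.

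Fold changes are MC38.T4 minus MC38 on the scale of log2(FPKM + 1), which understates changes of low genes. Genes with an FPKM of at least 1 in at least 5 of the 10 libraries were tested (11110 genes) with limma 3.58.1 in R 4.3.3, with trend and robust variance moderation, a group term only, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count applied a log2 limit of 1. Single genes and list means also had an exact permutation test over all assignments of 5 libraries. Of 34 gene lists, 25 with at least 5 tested genes were tested with limma's camera, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry, with adjustment over the 25 lists. Of 606 list symbols 601 were found in the table, 5 of them through synonyms in the RefSeq gene table of mouse assembly GRCm38.p6. That table is of another build than the authors', so it was used for names and for which genes neighbour each other, and no coordinates are given. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 handled tables, permutations and figures.

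The tests, the gene lists and the rule for naming genes were fixed before the data were examined. Named genes are Ssbp4, Ssbp2, Ssbp3, Ldb1 and Msln; the 12 largest rises and 12 largest falls among genes past the test with a mean FPKM of at least 5 and no overlap between groups, leaving out Gm and Rik models and ribosomal protein genes; all tested cholesterol biosynthesis genes; at most 2 rises and 2 falls of each other list described, or the member with the highest mean where none passed; and tested cell type markers with a mean FPKM of at least 5. Some genes that this rule picks are not reported here. The same code was tested on simulated data for these 11110 genes with 200 changed genes. It recovered 74% of genes set to change by 0.25 on the log2 scale and 99% of those set to change by 1, and 5.53% of its calls were unchanged genes. A simulated list shifted by 0.3 gave a camera adjusted p of 8.17e-40 and an unchanged list 0.819. The simulated genes varied independently and most were unchanged, whereas 86.0% of the tested genes passed in the data. These 2 camera values therefore do not show how camera performs on the real lists.

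Alternatives were a pseudocount of 0.1, no filter, a minimum FPKM of 5, rescaling to TPM, quantile normalization, a shift to equal medians, plain eBayes, array weights, the replicate number as a block, leaving out each library in turn, an exact rank-sum test, limma's treat against a fold of 1.5 and, added after seeing the data, leaving out the 2 libraries that stand apart. Tests for counts were not run because the table holds no counts. The human mesothelin transgene was not analysed here.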

Results

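RNA from cultured cells of 2 mouse tumour lines was sequenced as polyA-selected, strand-specific libraries, 5 from parental MC38 and 5 from MC38.T4. MC38 is a line that the treatment description and the library names call a colon carcinoma, while the tissue label and the design text call it melanoma. MC38.T4 was made from MC38 cells that had been transfected with human mesothelin, cloned, grown as a tumour in mice, returned to culture and cloned again from a cell with low mesothelin. The labels say that it grew like its parent in culture and faster in mice. The comparison therefore asks which genes differ between a tumour-passaged subclone and its parental line in culture, and the series title directs attention to Ssbp4 and to cholesterol biosynthesis. The table held FPKM for 54343 genes, of which 27746 were listed at 0 in every library. FPKM summed to between 442183 and 484461 per library, and between 10723 and 10938 genes per library reached an FPKM of 1. Read totals are not given in the sources used here, and the depth relative to MC38 replicate 1, read from the size of single-read steps, lay between 0.874 and 1.14. The labels do not say whether the 5 libraries of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

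MC38.T4 and MC38 differed across most of the transcriptome. Of 11110 tested genes, 9555 (86.0%) passed the limma test at an adjusted p under 0.05, 4790 higher and 4765 lower in MC38.T4. A change of at least 2-fold was found for 1906 genes (17.2%), of which 1113 rose and 793 fell. The groups did not overlap for 8598 genes (77.4%), against 0.794% by chance. The median size of the log2 change over all tested genes was 0.47, against a median SD within a line of 0.07. Correlations of log2 values across genes lay between 0.993 and 0.998 within a line and between 0.896 and 0.905 between lines. Library MC38 replicate 1 had the lowest sum of FPKM and MC38.T4 replicate 4 had the highest Malat1 (125 FPKM, against 53.1 to 75.9 in the other MC38.T4 libraries). Without these 2 libraries, a choice made after seeing the data, 9603 genes passed and 1904 changed at least 2-fold. Mitochondrial transcripts took 5.14% ± 0.86 of FPKM in MC38 and 5.71% ± 0.72 in MC38.T4 (SD, n = 5 each).

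Among the 12 named rises, Spp1, which encodes osteopontin, went from 12.4 ± 1.5 to 627.6 ± 63 FPKM (mean ± SD, n = 5 per line). The imprinted long noncoding RNA H19 went from 0.041 ± 0.049 to 47.1 ± 3.2 FPKM. The fibrillar collagen gene Col3a1 rose 38.4-fold to 247.4 ± 3.0 FPKM, and Ccl2, a chemokine that attracts monocytes, rose 35.4-fold to 184.6 ± 19 FPKM. The other genes of this group were Ptn (54.7-fold, to 45.0 FPKM), Mme, which encodes neprilysin (22.3 FPKM), Cdh26 (22.6 FPKM), the ferritin receptor gene Scara5 (22.5 FPKM), the water channel gene Aqp1 (20.4 FPKM), the PDGF receptor gene Pdgfrb (19.2 FPKM), the gelatinase gene Mmp9 (32.0 FPKM) and Gas1 (52.3 FPKM), all in MC38.T4. Their adjusted p from limma was at most 2.03e-14.

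Among the 12 named falls, Atf3, a stress-induced transcription factor, went from 40.99 ± 1.8 FPKM in MC38 to 0.032 ± 0.021 in MC38.T4. Cyba, which encodes the p22phox subunit of NADPH oxidase, stood at 16.0 ± 2.5 FPKM in MC38 and was listed at 0 in 4 MC38.T4 libraries and at 0.0335 in the fifth. Ppp1r15a, which directs dephosphorylation of eIF2alpha, fell from 253.6 ± 6.3 to 25.0 ± 7.3 FPKM, and Gadd45a fell from 356.2 ± 13 to 38.1 ± 13 FPKM. Gnpda2, a glucosamine-6-phosphate deaminase gene, fell from 11.3 ± 0.89 to 0.128 ± 0.037 FPKM. Fam171b fell 11.6-fold, the small nucleolar RNA host gene Snhg15 8.74-fold, Cdsn 17.2-fold, Slc5a4a 20.9-fold, Prr32 17.1-fold, Mamdc2 22.4-fold and the Ly49 family member Klra2 17.5-fold. The adjusted p of these 12 genes was at most 1.59e-07. Handling of reads shared by close relatives is not given, so values of Klra2, H2-T23, Ifit3 and the guanylate-binding genes are uncertain to that extent.

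Ssbp4, the gene of the series title, was higher in every MC38.T4 library. It belongs to a family of single-stranded DNA-binding proteins that bind the adaptor LDB1. Its FPKM was 4.84 ± 0.65 in MC38 and 27.9 ± 2.0 in MC38.T4 (SD, n = 5 each), a log2 fold change of 2.31 (SE 0.07, limma adjusted p = 5.5e-13, exact permutation p = 0.00794, two-sided, the smallest this test can give). Ssbp2 rose from 9.93 ± 0.53 to 18.9 ± 0.60 FPKM and Ldb1 from 31.1 ± 2.2 to 49.4 ± 2.6 FPKM. Ssbp3 stood at 17.7 ± 0.55 and 17.96 ± 0.46 FPKM (log2 difference 0.02, SE 0.03, adjusted p = 0.646). Of 12 tested genes of the SSBP and LIM-domain-binding list 6 rose, 3 fell and 3 did not pass, as adjusted over the list alone, and camera found no shift of the list (adjusted p = 0.621; 0.698 with an estimated correlation). Among the falls were the ubiquitin ligase gene Rlim (65.4 to 30.1 FPKM) and the LIM homeobox gene Isl1 (2.78 to 1.17 FPKM). Mouse Msln lay below the filter, at 0.080 ± 0.043 and 0.431 ± 0.069 FPKM, and was called only in the unfiltered fit (adjusted p = 6.94e-06), and the human transgene was not analysed here.

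**Figure D1:**
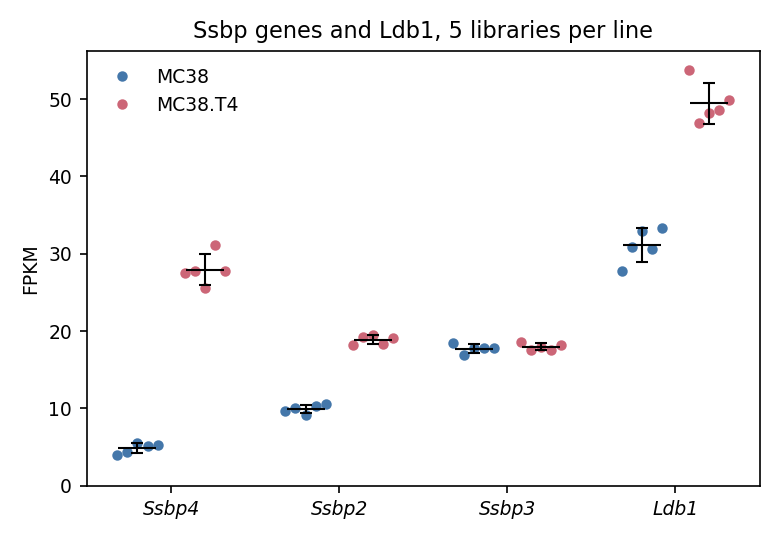
FPKM (vertical axis, linear) of Ssbp4, Ssbp2, Ssbp3 and Ldb1 in the 5 MC38 and 5 MC38.T4 libraries; points are libraries, long horizontal bars are means and whiskers are SDs. Ssbp4 averages 4.84 in MC38 and 27.9 in MC38.T4, while Ssbp3 averages 17.7 and 17.96.

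Cholesterol biosynthesis genes rose together. All 19 tested members of the list passed the test with a rise in MC38.T4, 14 of them at least 2-fold, and all 19 passed when adjusted over the list alone. Fdps, which makes farnesyl diphosphate, went from 21.9 ± 1.7 to 185.0 ± 8.2 FPKM (8.46-fold), Mvk, mevalonate kinase, from 1.90 ± 0.03 to 14.4 ± 0.47 (7.56-fold) and Msmo1 from 11.9 ± 1.0 to 63.2 ± 4.0 (5.29-fold). Hmgcs1 rose 2.28-fold. Other rises were those of Nsdhl (5.07-fold), Idi1 (4.85-fold), Acat2 (4.08-fold), Fdft1 (3.47-fold), Mvd (2.63-fold), Lss (2.53-fold), Dhcr7 (2.21-fold) and Cyp51 (2.14-fold). Sc5d and Pmvk rose 1.96-fold, Ebp 1.70-fold and Hsd17b7 1.29-fold. Sqle, squalene epoxidase, changed least, from 42.1 ± 1.0 to 50.5 ± 2.5 FPKM. The list had a median log2 change of 1.20 and passed camera against all other genes (adjusted p = 2.86e-06 with a preset correlation). With an estimated correlation the call was lost (adjusted p = 0.243). The mean of log2(FPKM + 1) over the list was 3.31 ± 0.02 in MC38 and 4.73 ± 0.05 in MC38.T4 (exact permutation p = 0.00794, two-sided, n = 5 each), highest in MC38.T4 replicate 4 (4.82). This exact p is the smallest the test can give. Lists that camera did not call reached it too, among them the SSBP, isoprenoid and NF-kB lists, so it does not set the cholesterol list apart.

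**Figure D2:**
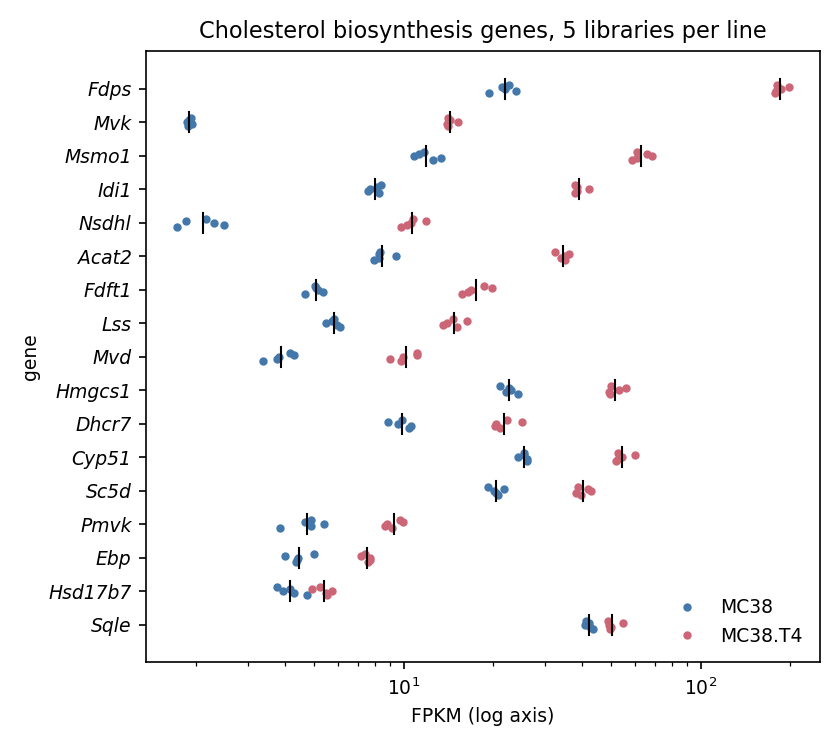
FPKM (horizontal axis, log scale) of 17 of the 19 tested cholesterol biosynthesis genes (rows, ordered by log2 fold change); points are the 5 libraries of each line and black ticks are means. Fdps shows the widest gap, 21.9 against 185.0, and Sqle the narrowest, 42.1 against 50.5.

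Most genes of the fatty acid list and of the SREBP and uptake list rose, while efflux genes went both ways. In the SREBP control and LDL uptake list 10 of 14 genes rose and 4 fell, as adjusted over the list alone. Its median log2 change was 1.01, and 7 genes rose and none fell at least 2-fold. The desaturase gene Fads2 rose 7.97-fold, from 15.2 ± 0.54 to 121.1 ± 3.1 FPKM, while the endosomal cholesterol transporter gene Npc1 fell from 24.7 to 12.7 FPKM and Mbtps2 from 15.0 to 9.52 FPKM. The camera call (adjusted p = 0.0442) was lost with an estimated correlation (adjusted p = 0.358), with a minimum FPKM of 5 (adjusted p = 0.0513) and with the replicate number as a block (adjusted p = 0.056, the highest over 20 alternatives, the lowest being 0.00944). In the list for fatty acid synthesis and desaturation 13 of 14 genes rose and none fell, 13 adjusted over the list alone (camera adjusted p = 0.000259; adjusted p = 0.243 with an estimated correlation). Scd2, a stearoyl-CoA desaturase gene, rose 9.98-fold, from 48.7 ± 1.9 to 486.2 ± 12 FPKM, and Elovl6 5.82-fold, to 29.4 FPKM. Of 9 tested genes for efflux, LXR targets and esterification 4 rose and 3 fell, as adjusted over the list alone (camera adjusted p = 0.621; 0.698 with an estimated correlation). Mylip rose from 3.08 to 11.1 FPKM and Lpcat3 from 10.5 to 30.2, while Apoe fell from 6.01 to 1.72 and Soat1, which esterifies cholesterol, from 42.9 to 21.7. In the isoprenoid branch 4 of 14 genes rose and 7 fell, as adjusted over the list alone. Its median log2 change was -0.14 and its mean 0.20, the mean set by Fdps and Idi1, and camera gave a direction down (adjusted p = 0.621; 0.698 with an estimated correlation) where fry gave up. Rabggta fell from 8.58 to 5.57 FPKM and Pdss1 from 24.5 to 17.1 FPKM.

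Most tested genes of the MHC class I and interferon lists rose in MC38.T4, while B2m, Jak2 and Cd74 fell. In the MHC class I list 18 of 21 genes rose and 2 fell, as adjusted over the list alone (camera adjusted p = 0.000136; adjusted p = 0.315 with an estimated correlation). The immunoproteasome gene Psmb9 rose 8.65-fold, from 3.64 ± 0.22 to 31.5 ± 0.72 FPKM, and the nonclassical gene H2-T23 9.49-fold, to 10.4 ± 0.70 FPKM. B2m, the light chain of class I molecules, fell from 2025 ± 79 to 1292 ± 58 FPKM, and the chaperone gene Canx from 268.1 to 250.3 FPKM. A run of 48 neighbouring tested genes on chromosome 17, from Rxrb to Tubb5, had a median log2 change of 0.63, with 34 rises and 8 falls. Which class I genes lie in it was not examined, so a shared rise of 1 locus was not separated from a rise of the list. In the type I interferon list 22 of 24 genes rose and 1 fell, as adjusted over the list alone (camera adjusted p = 3.86e-05; adjusted p = 0.358 with an estimated correlation). Zbp1 went from 0.217 ± 0.078 to 8.75 ± 1.1 FPKM and Ifit3 from 1.05 ± 0.23 to 14.5 ± 2.5, and Bst2 fell from 159.7 to 139.8. In the interferon gamma list 13 of 17 rose and 4 fell, as adjusted over the list alone. Gbp3 rose 4.72-fold and Gbp2 3.40-fold, while Jak2 fell from 33.6 to 17.6 FPKM and Irgm1 from 51.4 to 36.2 FPKM. This call (camera adjusted p = 0.0298) was lost with an estimated correlation (adjusted p = 0.375) and with a minimum FPKM of 5 (adjusted p = 0.143, the highest over 20 alternatives, the lowest being 0.00234). The mean of log2(FPKM + 1) over the type I list was highest in MC38.T4 replicate 4 (3.72, against 3.45 to 3.58 in the other MC38.T4 libraries). Of 4 tested MHC class II genes 3 rose, among them Rfx5 (2.34 to 7.62 FPKM) and Ifi30 (20.8 to 32.5), and Cd74 fell (2.50 to 0.947). Of 11 genes for cytosolic nucleic acid sensing 7 rose and 2 fell, 8 and 2 adjusted over the list alone (camera adjusted p = 0.162; 0.358 with an estimated correlation). Mavs rose from 21.0 to 34.3 FPKM and Ikbke from 0.415 to 1.35, while Cgas fell from 13.3 to 11.1 and Tbk1 from 22.8 to 19.6.

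Ligands that restrain or engage lymphocytes went both ways. Of 9 tested checkpoint ligand genes 5 rose and 4 fell, as adjusted over the list alone (median log2 change 0.15, mean -0.03, camera adjusted p = 0.908 with either correlation). Lgals9 rose 4.22-fold, from 7.80 ± 0.50 to 32.9 ± 1.6 FPKM, and Tnfrsf14 from 0.430 ± 0.059 to 4.70 ± 0.61. Nectin2 fell 3.78-fold, from 34.5 ± 0.51 to 9.12 ± 0.85 FPKM, and Pvr 3.32-fold, from 55.7 ± 2.9 to 16.8 ± 0.57. Of 8 NK receptor ligands and death receptors 5 rose and 3 fell, as adjusted over the list alone (camera adjusted p = 0.665; 0.698 with an estimated correlation). Fas rose from 1.56 to 5.98 FPKM and the NKG2D ligand gene Raet1e from 5.32 to 11.02, while the TRAIL receptor gene Tnfrsf10b fell from 17.7 to 6.17 and Cflar from 28.5 to 19.3. Of 16 chemokine and cytokine genes 13 rose and 3 fell, as adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.358 with an estimated correlation). Beside Ccl2, Ccl7 rose from 0.408 ± 0.11 to 16.8 ± 0.87 FPKM, while the lymphangiogenic factor gene Vegfc fell from 13.1 to 2.61 and Ptgs2 from 60.7 to 26.0. In the NF-kB list 6 of 15 genes rose and 7 fell, as adjusted over the list alone (camera adjusted p = 0.621; 0.752 with an estimated correlation). Vcam1 rose from 39.8 to 93.2 FPKM and Nfkb1 from 28.0 to 44.8, while Nfkbib fell from 56.5 to 14.6 and Traf1 from 31.4 to 11.9.

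Most tested matrix genes and fibroblast markers rose, and 16 of 18 epithelial genes lay below the filter. In the extracellular matrix list 12 of 16 genes rose, 10 at least 2-fold, and 4 fell, as adjusted over the list alone (camera adjusted p = 0.0104; adjusted p = 0.315 with an estimated correlation). Spp1 and Col3a1 led the rises, while Lamb1 fell from 80.8 to 38.1 FPKM and Timp2 from 389.3 to 249.5 FPKM. Of 13 markers of fibroblasts and pericytes 8 lay below the filter. All 5 tested markers rose, also adjusted over the list alone (camera adjusted p = 0.0129, and adjusted p = 0.243 with an estimated correlation). Pdgfrb went from 0.191 ± 0.035 to 19.2 ± 0.89 FPKM, Acta2 from 0.044 ± 0.027 to 2.77 ± 0.25, Dcn from 16.8 ± 1.6 to 58.1 ± 3.7, Pdgfra from 12.5 to 24.5 and Cspg4 from 5.58 to 6.61. The call of Cspg4 (adjusted p = 0.0127) was lost after rescaling to TPM (adjusted p = 0.0502) and with quantile normalization (adjusted p = 0.108), within a range of 0.00274 to 0.108 over 20 alternatives. Of 20 mesenchymal transition genes 12 rose and 4 fell, as adjusted over the list alone (camera adjusted p = 0.0874; 0.358 with an estimated correlation). With no filter the mesenchymal transition genes list passed (camera adjusted p = 0.00965, within a range of 0.00965 to 0.143 over 20 alternatives). Beside Mmp9, S100a4 rose 5.55-fold, from 214.8 ± 18 to 1193 ± 48 FPKM, while the transcription factor genes Snai2 and Zeb2 fell from 27.5 to 11.95 FPKM and from 30.8 to 14.9 FPKM. Both tested epithelial genes fell, Grhl2 from 3.59 ± 0.30 to 0.045 ± 0.009 FPKM and Tjp1 from 21.9 to 18.7. Of the intestinal genes Ephb2 rose from 3.08 to 6.82 FPKM, and of the melanocyte genes 1 was tested, Mitf, which rose from 0.781 to 1.74 FPKM. Of 18 lymphocyte markers 1 was tested, Lck (3.01 ± 0.12 and 2.81 ± 0.36 FPKM, adjusted p = 0.221). MC38.T4 replicate 4 held 3.43 FPKM of Lck and the other MC38.T4 libraries 2.55 to 2.81, and Lck was called lower in MC38.T4 without replicate 4 (adjusted p = 0.0126), without both libraries that stand apart (0.0192) and with quantile normalization (0.0041), within a range of 0.0041 to 0.419 over 19 alternatives. Of 18 myeloid markers 2 were tested and Cd68 fell, from 3.10 to 2.21 FPKM. None of 12 endothelial markers passed the filter, the highest being Eng at 0.405 and 0.400 FPKM.

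**Figure D3:**
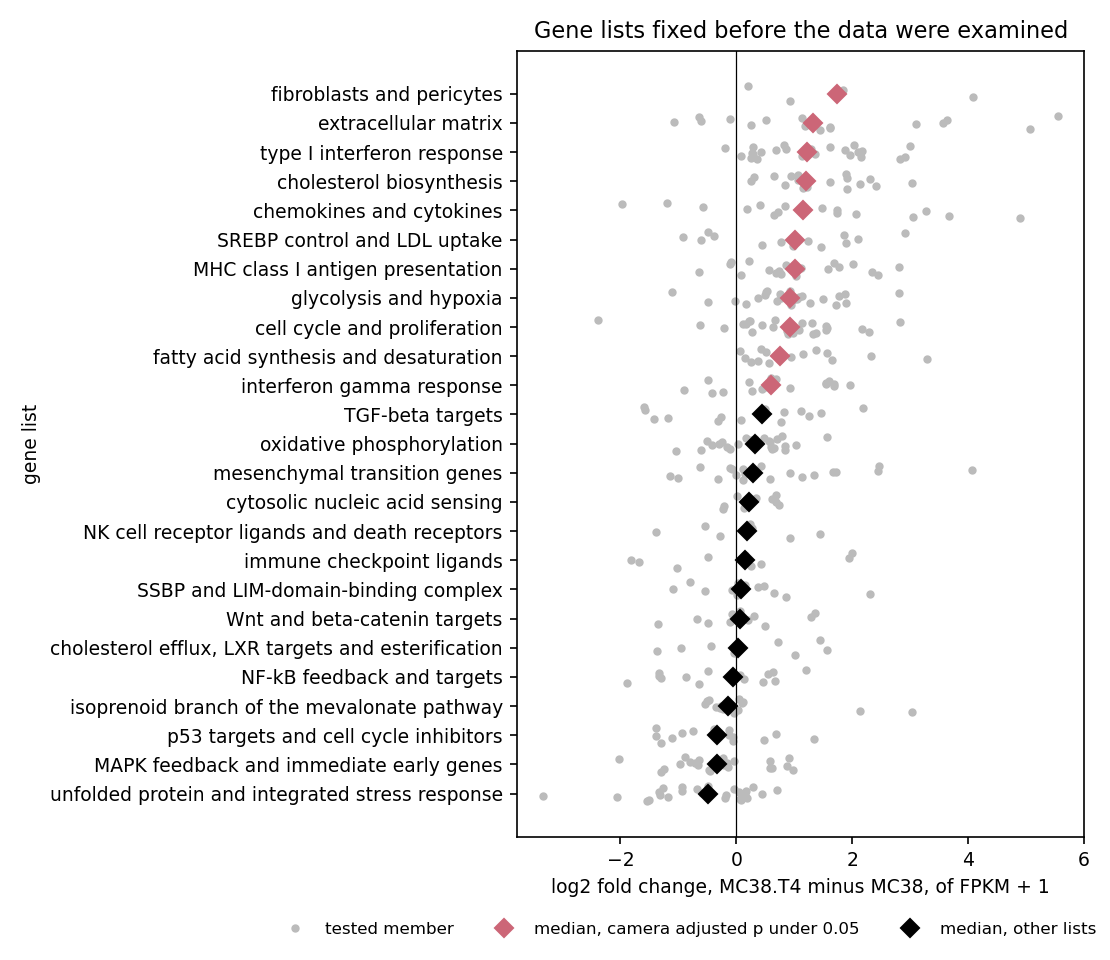
Log2 fold change of FPKM + 1, MC38.T4 minus MC38 (horizontal axis), of each tested gene (grey points) in the 25 lists with at least 5 tested genes, with list medians as diamonds, red where camera with a preset correlation gave an adjusted p under 0.05. The 11 red lists all have medians above 0; none of the 25 passed with an estimated correlation.

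Most tested cell cycle and glycolysis genes rose, though not Myc or Ndrg1, while p53 and stress-response lists held more falls than rises. In the cell cycle list 24 of 27 genes rose and 3 fell, as adjusted over the list alone (camera adjusted p = 3.86e-05; adjusted p = 0.277 with an estimated correlation). Ccne1, cyclin E1, rose 7.997-fold, from 6.49 ± 0.21 to 51.9 ± 0.53 FPKM, and Ccnb2 5.14-fold to 76.4 FPKM. Myc went the other way, from 301.6 ± 13 to 57.7 ± 9.2 FPKM, and Mcm7 fell from 91.4 to 59.1 FPKM. In the glycolysis and hypoxia list 21 of 24 rose and 2 fell, as adjusted over the list alone (camera adjusted p = 3.86e-05; adjusted p = 0.243 with an estimated correlation). Ankrd37 went from 0.230 to 7.66 FPKM and the phosphofructokinase gene Pfkl from 11.02 to 43.8, while Ndrg1 fell from 94.9 to 43.4 and Pfkp from 8.39 to 5.68. Of 25 oxidative phosphorylation genes 16 rose and 8 fell, as adjusted over the list alone (camera adjusted p = 0.111; 0.698 with an estimated correlation). With no filter the oxidative phosphorylation list passed (camera adjusted p = 0.0349, within a range of 0.0349 to 0.141 over 20 alternatives). Atp5c1 rose from 136.1 to 403.2 FPKM and Sdhb from 48.0 to 99.1, while Ndufa1 fell from 100.6 to 48.5 and Ndufa2 from 128.7 to 84.0. Of 15 p53 targets and cell cycle inhibitors 2 rose and 10 fell, as adjusted over the list alone (camera adjusted p = 0.0771; 0.277 with an estimated correlation). With no filter the p53 targets and cell cycle inhibitors list passed (camera adjusted p = 0.00439, within a range of 0.00439 to 0.097 over 20 alternatives). Cdkn2b rose from 34.1 to 87.9 FPKM and Sesn1 from 4.53 to 7.84, while Bbc3 fell from 16.6 to 5.76 and Plk2 from 235.2 to 90.2. In the list for unfolded protein and integrated stress responses 7 of 25 rose and 15 fell, as adjusted over the list alone (camera adjusted p = 0.0719; 0.698 with an estimated correlation). Beside Ppp1r15a, Ddit3, which encodes CHOP, fell 4.22-fold, from 335.1 ± 18 to 79.5 ± 6.1 FPKM, while Mthfd2 rose from 66.7 to 109.7 and Edem1 from 17.1 to 23.5. The unfolded protein and integrated stress response list passed without MC38.T4 replicate 4 (camera adjusted p = 0.0285), without both libraries that stand apart (0.0347) and with no filter (0.00938), within a range of 0.00938 to 0.09 over 20 alternatives.

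Signalling lists showed changes in both directions. Of 22 MAPK feedback and immediate early genes 6 rose and 15 fell, as adjusted over the list alone (camera adjusted p = 0.161; 0.698 with an estimated correlation). With no filter the MAPK feedback and immediate early genes list passed (camera adjusted p = 0.0234, within a range of 0.0234 to 0.242 over 20 alternatives). The EGF receptor ligand genes parted, Ereg rising from 10.1 to 19.8 FPKM and Areg falling 7.31-fold, from 6.97 ± 0.45 to 0.954 ± 0.098. Spry1 rose from 0.882 to 2.71 FPKM and Dusp4 fell from 14.3 to 5.19. Of 11 Wnt and beta-catenin targets 5 rose and 3 fell, as adjusted over the list alone (camera adjusted p = 0.708; 0.766 with an estimated correlation). Wnt5a rose from 11.99 to 32.4 FPKM and Sox9 from 6.06 to 16.2, while Znrf3 fell from 9.37 to 3.06 and Dkk2 from 1.90 to 0.821. Of 15 TGF-beta targets 8 rose and 6 fell, as adjusted over the list alone (camera adjusted p = 0.621; 0.698 with an estimated correlation). Bhlhe40 rose 5.58-fold to 19.3 FPKM and Id1 from 0.9503 to 4.39, while Inhba fell from 34.4 ± 7.2 to 10.5 ± 0.54 and Ltbp1 from 36.5 to 11.5.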

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

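The test of host fibroblasts was set before its result was seen; the tests of host leukocytes and endothelial cells, of the Ssbp4 locus, its paralogs and scaling, and of other splits of the libraries were chosen after. Among 362 groups of 5 libraries (each named gene, list mean and library measure in each line), 20 had 1 library far from the other 4, where chance alone gives about 1 in 20, or 18.1. Of the 20, 9 were in MC38.T4 replicate 4. There, Sqle stood at 54.9 FPKM, Cyp51 at 60.2, Tnfrsf14 at 3.65, Ptgs2 at 33.0, Traf1 at 13.8, Cdkn2b at 95.3 and Id1 at 3.31, the mean of log2(FPKM + 1) was 5.72 over the fatty acid list and 3.48 over the TGF-beta list. In MC38.T4 replicate 3, Mvk stood at 15.2 FPKM, Idi1 at 42.1 and Cyba at 0.0335. In MC38.T4 replicate 5, Cd74 stood at 1.11 FPKM. In MC38 replicate 1, Spp1 stood at 9.73 FPKM, Mavs at 22.7 and Traf1 at 29.9. In MC38 replicate 5, Aqp1 stood at 0.357 FPKM and Nectin2 at 35.4. Acat2 stood at 9.45 FPKM in MC38 replicate 3 and Ndufa1 at 113.0 in MC38 replicate 2. None of these genes changes its direction between the lines when any 1 library is left out.

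Ssbp4 rose by 2.31 on the log2 scale. Reads shared with Ssbp2 and Ssbp3 could have carried it in MC38.T4 to at most 9.2 FPKM, its MC38 level times the larger fold of the paralogs, while the lowest MC38.T4 library stood at 25.6. Its lowest log2 change over the 3 other scalings was 2.27, so the rise does not hang on the choice among them. They put the median of all genes between -0.05 and -0.03, too small a shift to remove such a change. The comparison therefore decides nothing further about scaling. A copy gain or other change shared by the whole locus, as the only cause, is argued against by its 40 nearest tested neighbours on chromosome 8 (gene order from GRCm38.p6), whose median log2 change was 0.51 (95% bootstrap interval 0.17 to 0.70), although Ssbp4 lies in a run of 52 neighbouring genes, from Nr2c2ap to B3gnt3, with a median of 0.55 and a highest window of 41 genes at 0.62, past the level that 5% of random gene orders reach, 11 of the 40 rose at least 2-fold, against 10.0% of all tested genes, and Fkbp8 rose by 2.09. A median over 40 genes cannot show a change shared by only a few genes around Ssbp4, so that stays open. A shared rise of the locus that adds to a change of Ssbp4 itself stays open, as does any effect of cloning, of transfection or of growth in mice, which this design does not separate.

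The fibroblast and matrix genes Pdgfrb, Col3a1, Dcn and Acta2 rose, in a line derived from a tumour grown in mice. Host fibroblasts carried over would bring Col1a1 and Col1a2 at levels near that of Col3a1, yet the higher of them in MC38.T4 reached 0.75% of the Col3a1 level (Col1a2, 1.86 ± 0.08 FPKM; Col1a1, 0.175 ± 0.032), and Thy1 was listed at 0 in all 10 libraries. Of the other genes such cells would bring, Sparc rose from 158.6 ± 6.0 to 303.8 ± 12.7 FPKM, and Col1a2 itself rose from 0.043 ± 0.014 FPKM, so what is argued against is host fibroblasts as the source of the Col3a1 level, not a trace of them. For host leukocytes and endothelial cells, the summed FPKM of 47 lymphocyte, myeloid and endothelial markers did not rise. The sum was 11.2 ± 0.67 in MC38 and 10.0 ± 1.0 in MC38.T4, where it stood at 4.05% of the Col3a1 level. That share decides nothing about the source of Col3a1, because marker levels do not tell how much Col3a1 such cells hold. The highest of the markers in MC38.T4 was Cd14 at 3.19 FPKM. Only 3 of the 47 markers, Lck, Cd68 and Cd14, passed the filter, and 0 rose, so these values leave a trace of such cells open. By the labels, MC38.T4 was cloned again from a cell after its return to culture. That step would carry no host fibroblasts, leukocytes or endothelial cells along if the clone was pure, and its purity was not tested.

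Of 100 splits of these 10 libraries into 5 and 5, 1, the real one, gave 9555 genes, and the highest other split gave 3. The same 1 of 100 splits gave 1906 genes changed at least 2-fold, and the highest other gave 3. All other splits held libraries of both lines on each side, so the difference between the lines entered their spread and kept their counts low. The counts argue against a chance assignment of these 10 libraries to the lines, but add nothing to the separation of the lines given above. Splits do not cover differences between cultures of 1 line.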

How the results depend on the processing

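Leaving out the 2 libraries that stand apart, and all alternatives for chromosome 10, were chosen after seeing the data. The count of changed genes (9555) lay between 7683 and 12725 over 21 alternatives, within 1.5 times. The count changed at least 2-fold (1906) lay between 1534 and 2508 except with treat against a fold of 1.5, a weaker limit by construction, which called 3474 (1847 rose, 1627 fell). Ssbp4 stayed past the threshold with log2 changes from 2.21 to 2.51 over 20 alternatives, and the cholesterol list with medians from 1.16 to 1.32, except that camera with an estimated correlation gave an adjusted p of 0.243 for it. Of the 25 lists, 11 passed camera; 0 passed with an estimated correlation (the lowest adjusted p was 0.243) and 25 passed fry, which does not compare a list with other genes. Over the 20 alternatives that keep the preset correlation the count lay between 8 and 16. The median of chromosome 10 lay between -0.52 and -0.43. Ssbp3, not called, turned to -0.0296 after rescaling to TPM and -0.0113 after a median shift. The cholesterol efflux, LXR targets and esterification list, not called, turned to a median of -0.0397 with a minimum FPKM of 5, -0.0129 after rescaling to TPM and -0.0006 without MC38.T4 replicate 4, and the isoprenoid list turned to up with fry (adjusted p = 7.06e-07); the cause was not tested. Same-numbered libraries did not deviate together (r from -0.13 to 0.14, over 0.1 in 2 of 5 pairs, and 2 of 10 libraries correlated best with their own number). The values thus gave no sign of pairing by number, and the labels do not say whether the numbers pair libraries. With a replicate block 9534 genes passed and 1904 changed at least 2-fold. No scaling moved the median of all genes by over 0.1. Genes below the filter were tested only in the unfiltered fit (12725 called of 26597), and with no read totals given no counting error could be attached to them.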

Other observations

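All tests in this part were chosen after results had been seen, as were the 24 gene families, which were defined by symbol and tested with camera against all other genes. Zinc finger genes named Zfp fell widely: of 313 tested, 220 fell and 44 rose, with a median log2 change of -0.42 (camera adjusted p = 5.43e-07; adjusted p = 0.862 with an estimated correlation). Zfp566 fell most, from 7.70 ± 0.78 to 1.66 ± 0.14 FPKM, and Zfp414 rose most, from 1.22 ± 0.23 to 6.87 ± 0.43. None of 10000 random lists matched on expression had a median as low (95% between -0.07 and 0.13), and the median was -0.52, -0.51 and -0.44 under the 3 other scalings. Random lists, here and for the families below, do not keep the correlation between genes of a family. Their counts therefore do not answer the loss of a call with an estimated correlation. Amino acid transporters of the Slc1, Slc7 and Slc38 families fell in 10 of 12 cases and rose in none (median -0.51, camera adjusted p = 0.0199; adjusted p = 0.862 with an estimated correlation), among them Slc38a7 (13.9 ± 0.17 to 5.69 ± 0.41 FPKM) and the cystine transporter gene Slc7a11 (9.49 ± 1.0 to 5.595 ± 0.73), while Slc7a5 stood at 95.6 and 93.6 FPKM (adjusted p = 0.581). Of 10000 matched lists 193 had a median as low. The symbol patterns of tubulins, ribosomal proteins and Rab genes were narrowed after their first results had been seen. With the pattern as first written, 13 of 16 tubulin genes rose, 3 fell, and camera did not pass (adjusted p = 0.0516); without the gamma-tubulin complex genes, 10 of 11 rose, 1 fell, and it did (adjusted p = 0.0199; adjusted p = 0.862 with an estimated correlation), so no call is made for tubulins. The patterns of the Zfp genes and the amino acid transporters were not narrowed. Before the narrowing of the others their camera adjusted p was 5.43e-07 and 0.0223. Only the adjustment over families could differ, so these values are no second check. The median of the transporters was -0.57, -0.50 and -0.54 under the 3 other scalings. The other 21 families did not pass camera. Among them, 9 of 14 small nucleolar RNA host genes fell and 4 rose (median -0.87, camera adjusted p = 0.288; adjusted p = 0.862 with an estimated correlation), and 1 of 10000 matched lists had a median as low.

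Chromosome 10 had the lowest median log2 change of any chromosome, -0.43 over 532 tested genes, of which 357 fell and 125 rose. In a run of 41 neighbouring tested genes from Gm46209 to Ahi1 (order from GRCm38.p6) the median was -1.0015 and the upper quartile -0.42, and 37 genes fell and 1 rose. Chance order is argued against, since none of 1000 random orders gave a run as far from 0 anywhere (permutation p = 0.001, the smallest they can give). Because the run was picked for its median, windows on chromosome 10 were also picked on every other gene and examined on the 20 genes between them. Of these, 15 fell in 1 case and all 20 in the other, against 42.9% of all placed genes and 357 of the 532 on chromosome 10. The windows were sought on this chromosome only, so its own share is the nearer comparison, and 15 of 20 does not set a run apart from it. Their medians were -0.73 (95% bootstrap interval -1.10 to -0.27) and -1.08 (-1.31 to -0.60), both under the median of all genes. The first interval takes in the median of the chromosome, -0.43, and the second does not. The first interval reaches above the limit set for this test, the lower quartile of all placed genes (-0.45), so how far strong genes add to the fall stays open. The least negative median of the more and the less expressed genes so held out was -0.72, as a lower copy number in MC38.T4 would give. Shared silencing would give it too, no DNA was measured, and both stay open. In all, 11 runs on 9 chromosomes passed the level that 5% of random orders reach, 5 of them up and 6 down.

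Imprinted genes were examined because H19 rose. Of 13 tested members 9 rose and 4 fell, so they did not all change in 1 direction. The values are gene totals that do not separate the parental alleles, so whether imprinting changed was not tested. At least 2-fold rises, H19, Cdkn1c, Dcn and Airn, made up 30.8%, and 25.0% of the 12 members without H19, against 10.0% of all tested genes, and an excess of rises stays open. Plagl1 (17.3 ± 1.1 to 2.27 ± 0.15 FPKM), which lies in the run on chromosome 10, fell at least 2-fold, and Igf2, the neighbour of H19, stood at 0.038 and 0.065 FPKM.

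Atf3 and Cyba were the 2 tested genes with a mean of at least 10 FPKM in MC38 and under 0.1 in every MC38.T4 library. No gene met the reverse, but H19 did without MC38 replicate 5 (0.1219 FPKM), and Gm14819 joined Atf3 and Cyba without MC38.T4 replicate 2. For Cyba, deletion or silencing that takes in its neighbours is argued against, since the lower of its 2 nearest tested neighbours, Zc3h18, changed by -0.18 and the other, Mvd, rose by 1.20. For Atf3 it cannot be told apart from a change of Atf3 alone, because Batf3 on 1 side fell (log2 change -1.4968) while the other neighbour, D730003I15Rik, rose by 0.84.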
